A study of Mus musculus with 4 samples.

How the data were processed

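RNA of the complete left hippocampus of 4 wild-type mouse samples, described in the labels as biological replicates, was measured on 1 array each. Per the labels' protocols, total RNA was extracted with a kit for lipid-rich tissue, treated with DNase, amplified and labelled with biotin. The deposited values are log2 intensities per probe set, made by the authors with RMA, per the submitters' processing notes; RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a set. The version, software and settings of that step are not given in the sources used here. The distributions of the 4 columns lie close together without being identical, and 24009 of 45101 probe sets hold the same value in at least 2 samples, 1464 of them in all 4. Such equal values lower the SD of the genes concerned and make gaps between the remaining values look large.

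The probe table paired 34958 probe sets with 1 gene symbol, 932 with several and 9211 with none, where 64 probe sets are controls. Symbols were brought up to date through the Entrez identifiers of the RefSeq table of assembly GRCm38.p6, which held 34754 of the single-symbol probe sets; 2 listed genes were renamed by hand. That table served only for names and for which genes are neighbours. Each of 18193 genes was represented by its single-symbol probe set with the highest mean, and probe sets with several symbols were not used to name genes.

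The gene lists, tests, background and naming rule were fixed before the data were examined. Of 531 distinct listed genes in 39 lists, 477 had a probe set of their own; the others, such as Grin1 and Ddx3y, were not analysed here. Background was the 95th percentile of the mean levels of the genes not expected in hippocampus, 44 of 48 measured, which came to 6.03; their median was 3.55. The place of each list's median among random lists was also computed and is not given, since probe sets differ in affinity.

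The spread of each probe set above background was tested with limma (lmFit with an intercept, eBayes with trend and robust fit): the residual variance over the fitted prior variance was taken as an F statistic with 3 residual and 2.12 prior degrees of freedom, with Benjamini-Hochberg adjustment at 0.05. For the lists, the deviations of the members from their own means were averaged per sample, and the SD of these 4 values was set against 10000 random lists matched on 20 bins of level, one-sided, for lists with at least 4 members above background, with the same adjustment over 30 lists. Agreement between arrays was taken as Pearson's correlation across genes and as the median absolute difference. Control probe sets gave the technical spread and the 3' minus 5' differences.

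A test of whether the probe sets of a gene agree was added after the planned test of spread had given no calls. For genes with 2 or more probe sets above background, the mean square between samples was divided by the mean square of probe set by sample, squeezed with limma's squeezeVar; a version without squeezing had been run first, and both counts are given. The 3' minus 5' difference of Gapdh as a covariate, and the omission of samples 15 and 17, were likewise added after the values had been seen.

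Named genes are the first 4 measured members of each list for levels, the 4 members with the largest SD for each list that passes, all measured sex-linked genes, and the 30 genes with the largest SD among called probe sets, of which there were none. Genes outside this rule are said to be so where they appear.

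The tests were tried on simulated data. The test of spread found 40.5% of 200 planted probe sets at a 3-fold SD when true variances did not differ between probe sets, and 0% when they differed as much as fitted. At a 10-fold SD it found 97.5% and 0.5%. For the test of lists, 5% of simulated lists of 12 genes had an unadjusted p under 0.05 against random lists with no shift. The share was 99% with a shift of 0.2 on the log2 scale in 1 sample and 100% with 0.4. These shares are without the adjustment over lists used for the real lists, so they do not give the power after it. Simulated genes shared no pattern apart from the shift, so the 5% is no rate of false passes for genes that vary together. The test of probe sets found 8.5% of 200 genes with a shared pattern of SD 0.2 and 89% at SD 0.5, with 0 and 4 false calls among 3062 genes. Values were permuted within each probe set there, so probe sets shared no pattern apart from the planted one. Those false calls are thus no rate for real arrays, whose probe sets can move together for technical reasons.

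Alternatives covered the background limit, the filter on dim genes, the choice or median of probe sets, quantile normalization again, median centring, the prior of the variances, scaling by squeezed SD, the threshold and each sample left out in turn. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.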

Results

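Transcript levels were measured in the complete left hippocampus of wild-type mice with an Affymetrix expression array. The 4 samples, numbered 11, 13, 15 and 17 in the labels, are described as biological replicates and form 1 group. The series title names protein and toponomic methods, which map where proteins lie in a tissue, beside the array, and data of those kinds are not analysed here. The deposited values are log2 intensities for 45101 probe sets, with a median between 4.67 in sample 17 and 4.71 in sample 11. The number of arrays limits the precision of every value below. With a single group, the questions were which gene groups were detected in this tissue and which genes and gene groups differed between the samples. All levels are means ± SD of log2 intensity (n = 4) of the gene's probe set with the highest mean. Other probe sets of a gene can vary more: one above background had an SD of 1.26 for Hk1, 1.18 for Gad1, 1.07 for Camk2a and 0.64 for Slc1a3, lowest in sample 17 each time, examples chosen after their values were seen.

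Neuronal markers and presynaptic genes were detected without exception among those measured. All 15 neuronal markers and all 15 presynaptic genes lay above a background of 6.03, the 95th percentile of 44 genes of testis, liver, skin and other tissues. Snap25, a SNARE protein of vesicle fusion, had a level of 11.44 ± 0.027, Syt1, the calcium sensor of release, 11.87 ± 0.021, Stmn2, a microtubule regulator, 11.08 ± 0.052, and Nefl, the light neurofilament, 11.32 ± 0.024. Among presynaptic genes, the vesicle protein Syp had a level of 11.13 ± 0.15, the active zone scaffold Bsn 10.19 ± 0.054, Syn1 11.30 ± 0.093 and Vamp2 10.72 ± 0.048. Of the glutamate receptor and postsynaptic density genes, 14 of 16 were above background, with the scaffold Dlg4 at 9.04 ± 0.15, the AMPA receptor subunit Gria1 at 11.33 ± 0.013 and the kinase Camk2a at 11.78 ± 0.040. The NMDA receptor subunit Grin2a was under background at 3.89 ± 0.10 by its only probe set, which does not show that it was absent. All 10 GABA receptor genes were above it, among them Gabra5 at 8.70 ± 0.11, Gabbr1 at 11.23 ± 0.013, the postsynaptic anchor Gphn at 8.71 ± 0.11 and Gabra2 at 7.12 ± 0.61. The 13 synaptic adhesion genes were all detected too, with Nlgn1 at 7.07 ± 0.052, Ncam1 at 9.99 ± 0.040, Cadm1 at 9.91 ± 0.057 and Nrxn2 at 9.58 ± 0.11. Of the neuromodulator receptors, 9 of 14 passed background, with the cannabinoid receptor Cnr1 at 9.57 ± 0.061, the muscarinic receptor Chrm1 at 10.27 ± 0.11, the serotonin receptor Htr1a at 7.12 ± 0.28 and the nicotinic subunit Chrna7 at 8.35 ± 0.095.

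Some or all markers of each hippocampal field were above background. The share was 62.5% for CA3 and 66.7% for dentate granule cell markers, against 49.5% of all genes and 61.5% of neocortex and subiculum markers. Such shares alone do not set CA3 and dentate markers apart. All 6 CA1 markers were above background, with Wfs1 at 8.88 ± 0.19, Fibcd1 at 8.74 ± 0.13, Man1a at 8.54 ± 0.15 and Mpped1 at 9.29 ± 0.13. In CA2, 5 of 6 passed, including Rgs14 at 9.75 ± 0.17 and Pcp4 at 10.58 ± 0.11. In CA3, 5 of 8 passed, with the kainate receptor subunit Grik4 at 6.40 ± 0.070, Bok at 9.16 ± 0.15 and Cpne4 at 8.39 ± 0.064, while Iyd was under background at 5.34 ± 0.18. Of the dentate granule cell markers, 8 of 12 passed: Dsp had a level of 7.80 ± 0.19, C1ql2 of 8.96 ± 0.15 and the calcium buffer Calb1 of 9.94 ± 0.058, and the transcription factor Prox1 lay under background at 5.76 ± 0.073. All 13 interneuron markers were detected, among them the GABA-synthesising enzymes Gad1 at 10.24 ± 0.037 and Gad2 at 8.23 ± 0.018, the peptide Sst at 10.70 ± 0.096 and the calcium buffer Pvalb at 9.19 ± 0.23. Genes of neurogenesis and proliferation were at 7 of 13, and Dcx of immature neurons (5.85 ± 0.11), Eomes (4.72 ± 0.049) and the cycling marker Mki67 (3.01 ± 0.14) were under background while Sox11 stood at 6.09 ± 0.070.

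Glial genes were detected widely and vascular genes in part. All 14 astrocyte markers were above background, with the filament protein Gfap at 10.29 ± 0.23, the water channel Aqp4 at 9.14 ± 0.074 and the glutamate transporters Slc1a2 and Slc1a3 at 11.93 ± 0.094 and 9.71 ± 0.12. All 12 myelin genes passed as well, and the structural myelin protein Mbp had a level of 12.05 ± 0.064, Mog of 6.48 ± 0.45, Mag of 8.66 ± 0.32 and Mobp of 10.27 ± 0.31. Oligodendrocyte precursor markers were at 6 of 8, with Pdgfra at 8.06 ± 0.14 and Olig1 at 9.78 ± 0.17. Microglial markers were at 10 of 13, with the receptors Cx3cr1 at 7.65 ± 0.040 and Csf1r at 9.89 ± 0.15 and the complement gene C1qa at 8.46 ± 0.19, while Aif1 lay under background at 5.90 ± 0.13. Of endothelial markers 7 of 11 passed, with Cldn5 at 8.15 ± 0.22 and Flt1 at 8.15 ± 0.053 above background and Pecam1 under it at 4.40 ± 0.28. Mural markers were at 4 of 10, with Rgs5 at 9.20 ± 0.15, and meningeal markers at 6 of 14, with Ptgds at 11.30 ± 0.30 and Col1a1 under background at 3.98 ± 0.038.

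The measured markers of the choroid plexus, ependyma, blood and hypothalamus were mostly under background. Of the choroid plexus markers 1 of 13 passed: Ttr, the thyroxine carrier, had a level of 7.65 ± 1.5, while Kl stood at 5.41 ± 0.33 and Folr1 at 3.79 ± 0.12. Of the ependymal markers 1 of 10 passed, Rarres2 at 6.60 ± 0.048, and the cilium regulator Foxj1 had a level of 3.83 ± 0.067. Erythroid markers were at 1 of 6 and leukocyte markers at 1 of 12, with the globin gene Hba-a1 at 3.77 ± 0.051 and the leukocyte gene Ptprc at 4.59 ± 0.17. Only 6 of 11 listed erythroid genes were measured. The globin genes Hbb-b1, Hbb-bs and Hbb-bt had no probe set of their own, so the count leaves the share of blood open. The hypothalamic and pituitary peptides were at 1 of 11, with Oxt at 7.24 ± 0.064 and Avp at 3.71 ± 0.30. Thalamic markers were at 5 of 11, striatal markers at 5 of 11 and markers of neocortex and subiculum at 8 of 13. Of their first 4 members, Prkcd (6.53 ± 0.17) and Ntng1 (7.64 ± 0.10) of thalamus, Ppp1r1b (7.33 ± 0.11) and Rgs9 (7.42 ± 0.13) of striatum and Rorb (6.61 ± 0.036), Cux2 (7.22 ± 0.072) and Lamp5 (8.54 ± 0.15) of neocortex were above background. Tcf7l2 (4.01 ± 0.013), Rgs16 (3.81 ± 0.17), Drd2 (4.39 ± 0.12), Drd1 (4.66 ± 0.063) and Tbr1 (5.61 ± 0.069) were under it.

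Genes of energy supply and translation were all above background, at 16 of 16 for oxidative phosphorylation, 9 of 9 for glycolysis and 13 of 13 for ribosomal proteins. The complex I gene Ndufa1 had a level of 11.44 ± 0.042, Sdha of 10.54 ± 0.026, the glycolytic genes Hk1 and Aldoa of 10.45 ± 0.066 and 12.53 ± 0.015, and Rpl4 of 11.68 ± 0.11. Immediate early genes were at 13 of 16, with Egr1 at 10.69 ± 0.14 and Nr4a1 at 9.05 ± 0.17, glucocorticoid-responsive genes at 10 of 12, with Fkbp5 at 8.59 ± 0.021, clock genes at 13 of 15, with Per1 at 8.34 ± 0.15 and Arntl at 7.24 ± 0.15, and chaperones at 11 of 12, with Hsph1 at 10.52 ± 0.12. Interferon-responsive genes were detected in 2 of 11 cases, and Ifit1 had a level of 3.97 ± 0.045 and Irf7 of 4.53 ± 0.067. Of the major histocompatibility complex, 3 of 8 genes passed, among them the class I genes H2-D1 at 8.98 ± 0.19 and H2-K1 at 8.71 ± 0.29. Housekeeping genes were at 8 of 9, with Actb at 12.05 ± 0.10 and Hprt at 9.71 ± 0.054. Among the sex-linked genes, Xist, which silences an X chromosome in females, was under background at 4.14 ± 0.055, and of the Y-linked genes Eif2s3y was above it at 6.44 ± 0.15 while Kdm5d stood at 5.58 ± 0.19 and Uty at 3.92 ± 0.24. Over the whole array 9006 of 18193 genes, or 49.5%, were above background. A level under background does not show that a gene was absent. Because the signal of a probe set depends on its affinity, levels of different genes are not ranked, and of the background genes themselves Prm1 (6.08 ± 0.075), Krt1 (6.47 ± 0.19) and Lor (7.10 ± 0.21) lay above the limit; Krt1 and Lor were named after their values were seen.

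**Figure D1:**
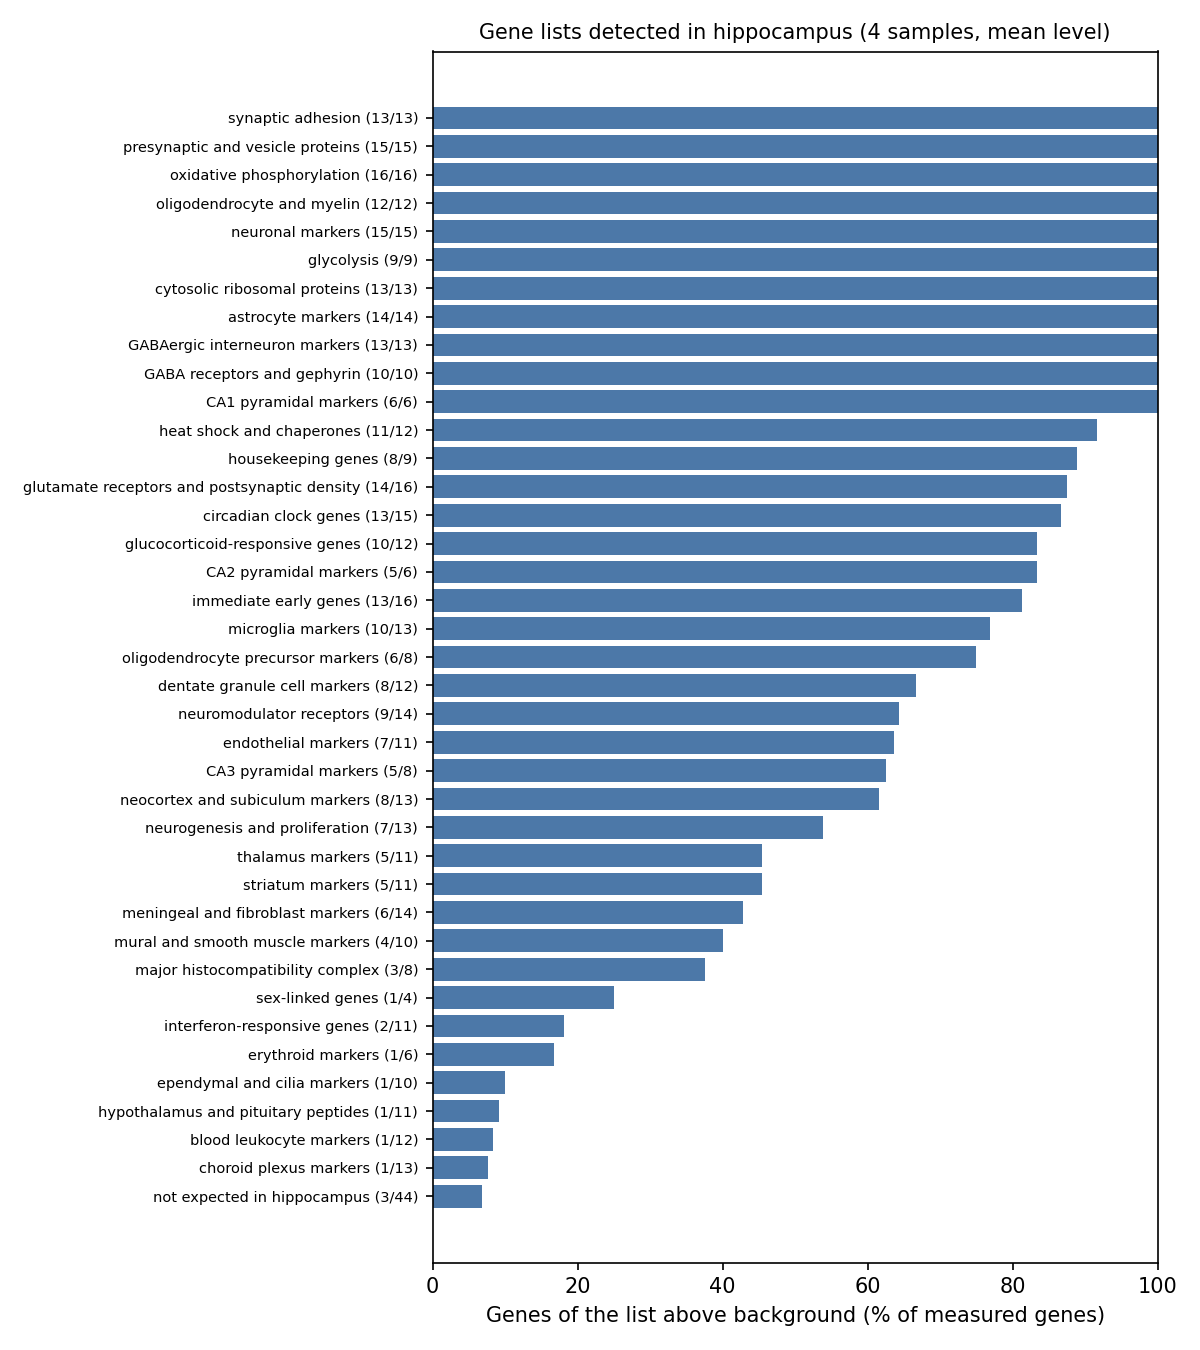
Share of the measured genes of each list with a mean log2 level above background, in percent (horizontal axis), per list (vertical axis; above over measured in parentheses), from the mean of 4 samples. Neuronal, presynaptic, astrocyte and myelin lists reach 100%, and the choroid plexus list stands at 7.69%.

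The arrays resembled each other closely. Across the 9006 genes above background, which are not independent replicates, Pearson's correlation across genes lay between 0.990 and 0.994 for the 6 pairs of samples, and in each pair between 5.96% and 9.74% of genes had exactly equal values. The median absolute difference was smallest between samples 13 and 15, at 0.0713 on the log2 scale, and largest between samples 11 and 17, at 0.116, with a median of 0.0813 over the pairs, or 0.103 without sample 13. The bacterial controls that are added ready-labelled before hybridisation varied less than the tissue's own genes over the 4 samples. Their median SD was 0.0467 over 18 probe sets, against 0.0863 for genes above background. Without sample 11 the median SD of the controls was 0.0238, and that of the genes without this sample is not given here.

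The 5' ends of transcripts gave less signal in samples 15 and 17. For Gapdh, a glycolytic enzyme whose transcript the array reads at several positions, the 3' minus 5' difference was 0.62 in sample 11, 0.62 in sample 13, 2.64 in sample 15 and 3.79 in sample 17. For beta-actin, a cytoskeletal protein, it was 1.10, 1.25, 1.93 and 2.33 in the same order. The hybridisation controls bioB, bioC, bioD and cre kept this difference within ranges of 0.0385 to 0.0846. Among 155 probe sets of any gene with an SD above 0.5, 138 were lowest in sample 17, 102 highest in sample 11 and 45 highest in sample 13, and the first principal component of all probe sets above background held 63.5% of the variance. These differences have no test, since each sample is a single array.

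**Figure D2:**
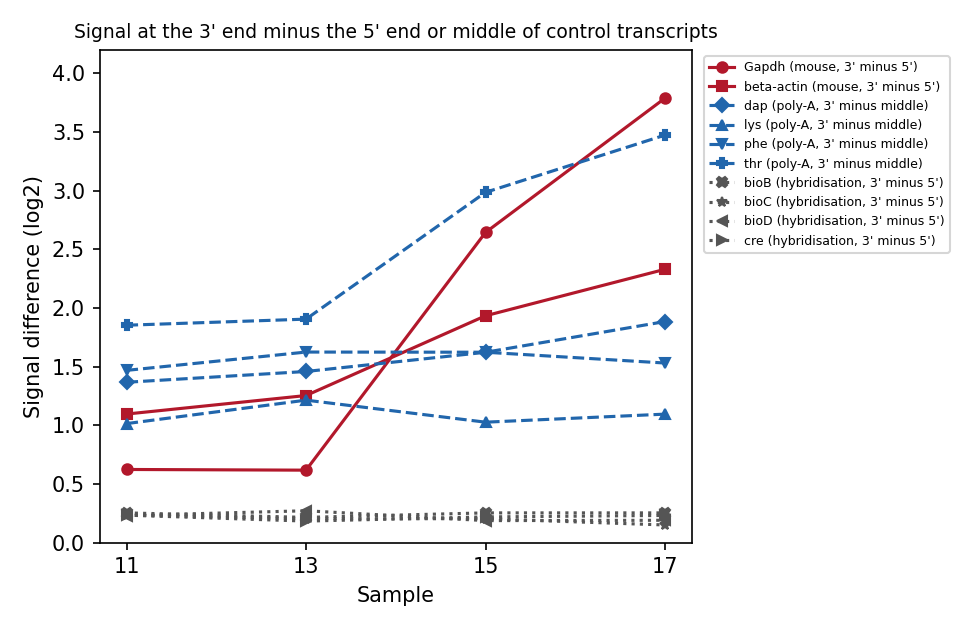
Signal at the 3' end minus that at the 5' end or middle of control transcripts (vertical axis, log2) in each of the 4 samples (horizontal axis), with a line per control. The mouse Gapdh line goes from 0.62 in sample 11 to 3.79 in sample 17, and the hybridisation controls stay within 0.0846.

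No single probe set passed the planned test for a spread larger than usual at its level. With limma, 0 of 14924 probe sets passed at an adjusted p of 0.05, the smallest adjusted p being 0.884, and 409 had an unadjusted p under 0.05 where 746 were due by chance. The largest spreads among listed genes belonged to Ttr, whose 3 probe sets above background were all highest in sample 13: the one with the highest mean stood at 7.36 in sample 11, 9.84 in sample 13, 6.86 in sample 15 and 6.54 in sample 17. Adjusted over the list alone, those 3 of 3 probe sets passed for the choroid plexus list, and 0 passed in each of the other 37 lists and 0 of 514 over all listed genes together. On simulated data with variances spread as fitted, the test found 0% of 200 probe sets with the SD raised 3-fold and 0.5% with it raised 10-fold, so a count of 0 does not show that genes were alike.

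Myelin genes differed together between the samples and were higher in sample 13. All 12 of the 12 members above background were highest there, and the list mean deviated by -0.22 in sample 11, 0.40 in sample 13, -0.032 in sample 15 and -0.15 in sample 17, a 1.54-fold span between samples 13 and 11. Mog, a surface protein of myelin, stood at 6.003, 7.07, 6.54 and 6.30 in samples 11, 13, 15 and 17, and the lipid enzymes Ugt8a and Fa2h went from 7.15 and 7.75 in sample 11 to 7.87 and 8.45 in sample 13. Mag, an adhesion protein of myelin, went from 8.45 to 9.12. Among 10000 random lists matched on level, none had as large a spread, so the unadjusted p was 1e-04, the smallest they can give, and the adjusted p 0.001. Samples 11 and 13 both had a Gapdh 3' minus 5' difference of 0.62, and with that difference as a covariate the adjusted p was 0.00075. Without sample 13 it was 0.119, and over 11 settings it ran from 0.0006 to 0.119.

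Chaperones were also highest in sample 13, for 10 of 11 genes. The list mean deviated by -0.10 in sample 11, 0.18 in sample 13, -0.095 in sample 15 and 0.022 in sample 17, a 1.22-fold span, with an adjusted p of 0.001 against random lists. Cryab, a small heat shock protein, went from 7.87 in sample 11 to 8.99 in sample 13, and the inducible Hspa1b from 7.89 to 8.58. The mitochondrial co-chaperonin Hspe1 stood at 9.51 and 9.89, and Hspa5 of the endoplasmic reticulum at 9.95 and 10.11. The adjusted p was 0.00075 with the 3' minus 5' covariate and 0.276 without sample 13, within a range over settings of 0.0006 to 0.276.

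Immediate early genes, which neurons switch on within minutes of activity, were higher in samples 13 and 17 than in samples 11 and 15. The 13 members deviated by -0.19 in sample 11, 0.12 in sample 13, -0.097 in sample 15 and 0.17 in sample 17, with an adjusted p of 0.001 against random lists and a 1.28-fold span. Fos stood at 7.68, 8.30, 7.502 and 8.88 in samples 11, 13, 15 and 17, and Arc, which acts at synapses, at 8.01, 8.82, 8.15 and 8.66. The phosphatase Dusp1 was lowest in sample 11 at 7.37 and highest in sample 17 at 8.26. Junb went another way between these samples, at 6.68, 7.07, 6.58 and 6.46. The list passed with each sample left out and with the 3' minus 5' covariate (0.00075), with adjusted p of 0.0006 to 0.012 over the settings.

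The glucocorticoid-responsive list had a similar order, at -0.15 in sample 11, 0.083 in sample 13, -0.092 in sample 15 and 0.16 in sample 17, with an adjusted p of 0.00225 and a 1.24-fold span between samples 17 and 11. The kinase Sgk1 stood at 8.88, 9.30, 8.95 and 9.62, Ddit4, an inhibitor of mTOR signalling, at 8.49, 8.82, 8.20 and 8.87, and the metallothionein Mt2 at 10.39, 11.00, 10.92 and 11.07. The transcription factor Zbtb16 ran against its list and was lowest in sample 17, at 7.58 against 8.16 in sample 11. Fkbp5, a co-chaperone of the glucocorticoid receptor, had an SD of 0.021. The call was kept with the 3' minus 5' covariate (adjusted p 0.00075) and lost when each gene was divided by its squeezed SD (adjusted p 0.135), in a range of 0.0006 to 0.135.

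CA1 and granule cell markers differed between the samples, and CA2 and CA3 markers did not pass (adjusted p 0.673 and 0.974). The 6 CA1 markers deviated by -0.077 in sample 11, 0.053 in sample 13, 0.14 in sample 15 and -0.12 in sample 17 (adjusted p 0.0319), and the POU transcription factor Pou3f1 stood at 8.58, 8.96, 9.14 and 8.46, Wfs1 of the endoplasmic reticulum at 8.87, 8.87, 9.12 and 8.67. The 8 dentate markers deviated by -0.061 in sample 11, -0.032 in sample 13, -0.070 in sample 15 and 0.16 in sample 17 (adjusted p 0.0266), with Plk5 at 7.11 in each of samples 11, 13 and 15 and 7.62 in sample 17, and Stxbp6, a SNARE-binding protein, at 9.64, 9.59, 9.53 and 9.97. The sample with the highest dentate mean, 17, also had the highest 3' minus 5' difference, and with it as a covariate the adjusted p was 0.0163 for CA1 and 0.036 for dentate markers. Neither call was kept without sample 15 (adjusted p 0.174 and 0.0592), without samples 15 and 17 (0.196 and 0.894) or after division by the squeezed SD (0.408 and 0.135), and the dentate call was also lost without sample 17 (0.899) and with the median over a gene's probe sets (0.13). Without sample 15 the SD of the dentate list was 0.127 against 0.11 with it, so it did not shrink, and that of CA1 was 0.09 against 0.121. Over the settings the adjusted p ran from 0.0085 to 0.408 for CA1 and from 0.009 to 0.899 for dentate markers.

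Microglial markers were lowest in sample 11 and highest in sample 15, with deviations of -0.13 in sample 11, 0.036 in sample 13, 0.12 in sample 15 and -0.022 in sample 17 over 10 genes and an adjusted p of 0.0266. The complement genes C1qb and C1qc went from 8.02 and 7.91 in sample 11 to 8.51 and 8.32 in sample 15, and the homeostatic marker Tmem119 from 6.90 to 7.37. The purinergic receptor P2ry12 had another order, at 6.21, 6.15, 6.08 and 5.67. With the 3' minus 5' covariate the adjusted p was 0.0163. The call was lost without sample 11 (adjusted p 0.171), without sample 15 (0.0761) and after division by the squeezed SD (0.227), in a range of 0.0006 to 0.227. The SD of the list, 0.107, was 0.0617 without sample 11 and 0.11 without sample 15.

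Clock genes and ribosomal protein genes also passed, though not in most other settings. Clock genes deviated by -0.018 in sample 11, -0.14 in sample 13, 0.084 in sample 15 and 0.074 in sample 17 (adjusted p 0.0186), and Dbp, a rhythmic transcription factor, stood at 8.02, 7.29, 8.48 and 8.37, the repressor Ciart at 6.05, 5.74, 6.27 and 6.43, Nr1d1 at 7.32, 7.03, 7.03 and 6.64 and Per2 at 6.43, 6.66, 6.93 and 6.98. Of the 13 members 7 were lowest in sample 13 and 2 were highest there, among them Arntl at 7.45. Nr1d1 also ran against the list and was lowest in sample 17. Ribosomal protein genes deviated by -0.073 in sample 11, -0.0056 in sample 13, 0.050 in sample 15 and 0.029 in sample 17 (adjusted p 0.0407), with Rps6 at 6.15, 6.49, 6.56 and 6.68 and Rpl27 at 10.47, 10.66, 10.74 and 10.70. With the 3' minus 5' covariate neither passed (adjusted p 0.0743 and 0.0771 against random lists). The SD was then 0.0714 for clock genes and 0.0434 for ribosomal protein genes, against 0.104 and 0.054 without it. The clock call was lost without sample 13 (0.786) or 15 (0.0662), and the ribosomal call without sample 11 (0.266) or 15 (0.103), with ranges over the settings of 0.0006 to 0.786 and 0.0142 to 0.421. The clock SD of 0.104 was 0.0561 without sample 13 and 0.107 without sample 15, and the ribosomal SD of 0.054 was 0.0282 without sample 11 and 0.0518 without sample 15.

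**Figure D3:**
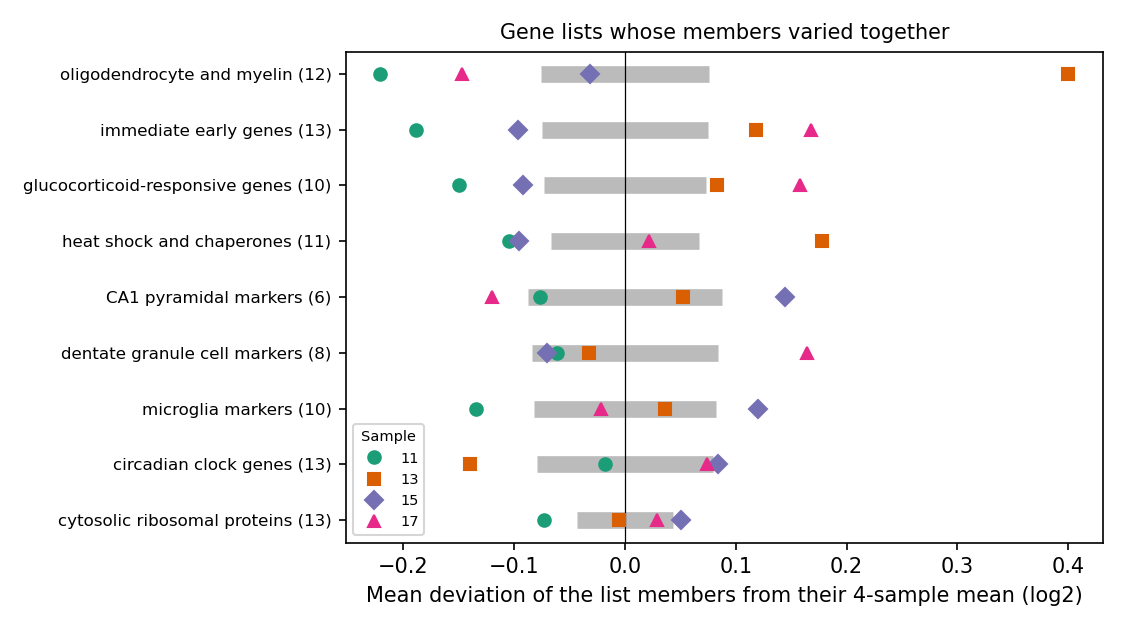
Mean deviation of the members of each passing list from their own mean over the 4 samples (horizontal axis, log2), a point per sample; grey bars reach to the 95th percentile of the SD of random lists on either side of 0, and the number of genes stands in parentheses. The myelin point of sample 13 lies at 0.40.

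Of 30 lists tested, 9 passed, 13 had an unadjusted p under 0.05, and 8 had fewer than 4 members above background and were not tested. Astrocyte markers deviated by -0.085 in sample 11, 0.035 in sample 13, 0.027 in sample 15 and 0.023 in sample 17 and did not pass (adjusted p 0.179). Meningeal markers, at 0.16 in sample 11, had an adjusted p of 0.0534, and oligodendrocyte precursor markers, at 0.11 in sample 13, one of 0.0731. The neuronal list had an SD of 0.0316 and an adjusted p of 0.53, and the presynaptic, glutamate receptor, GABA receptor, interneuron and adhesion lists did not pass either. In 1 other setting each, the glutamate receptor and astrocyte lists passed (median over a gene's probe sets), as did the GABA receptor list (without sample 11). Mural and oligodendrocyte precursor markers passed in 3 other settings each, and meningeal markers in 6. The count fell to 4 without sample 15 and to 4 with genes divided by their squeezed SD. Genes are not independent replicates, so these tests describe the 4 samples.

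**Figure D4:**
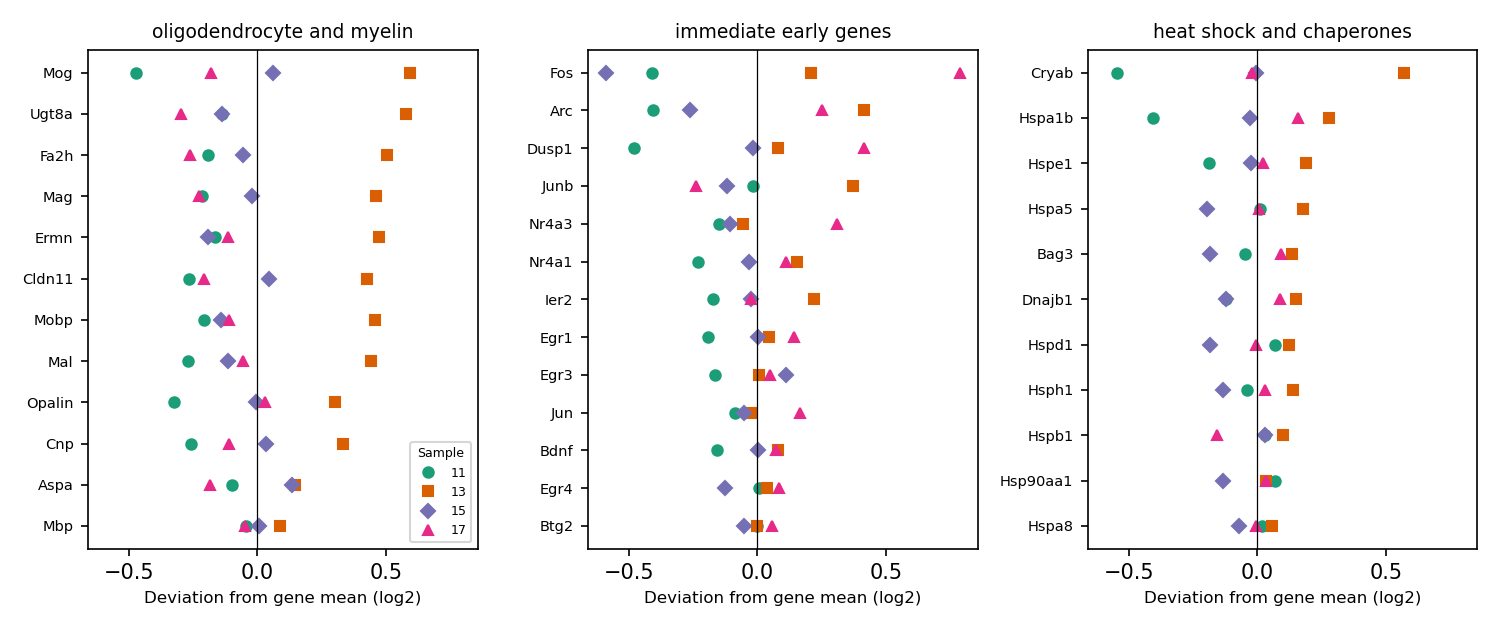
Deviation of each gene from its own mean over the 4 samples (horizontal axis, log2) for the myelin, immediate early and chaperone lists, a row per gene and a point per sample. In the myelin panel all 12 genes have sample 13 farthest to the right.

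Genes with several probe sets gave a further comparison, added after the planned test had given no calls: whether the probe sets of a gene agreed on differences between the samples. With limma's squeezed variances, 19 of 3062 genes passed at an adjusted p of 0.05, and 564 had an unadjusted p under 0.05. Chance alone would put a share of 0.05 of the genes under that limit. Probe sets of a gene read the same RNA on the same array and are not independent replicates. The p-values thus measure how far probe sets agree, which a technical shift of 1 sample could also give. Whether probe sets of a gene share probes was not tested. The differences of Ttr in samples 11, 13, 15 and 17 from its mean were -0.21, 2.45, -0.69 and -1.55 over 3 probe sets (adjusted p 0.000121 by limma). Those of Dbp were -0.034, -0.64, 0.38 and 0.30, those of the chaperones Cryab and Hspa1b -0.47, 0.58, -0.080 and -0.036 and -0.44, 0.36, -0.072 and 0.15, and those of Pou3f1 -0.21, 0.20, 0.36 and -0.36. Slc2a1, the glucose transporter of brain endothelium, had -0.15, -0.073, 0.045 and 0.17. These values rose from sample 11 to sample 17, as did the 3' minus 5' difference of beta-actin. The test of probe sets was not run with a 3' minus 5' covariate, nor without samples 15 and 17. The genes from here on, other than Mobp, were named after their values were seen. Nfkbia, an inhibitor of NF-kappaB, had -0.12, -0.023, -0.17 and 0.32 over 4 probe sets. Outside the fixed lists, the imprinted long non-coding RNA Meg3 had 0.24, -0.17, -0.041 and -0.038 over 11 probe sets, the actin-severing protein Gsn -0.11, 0.21, 0.0066 and -0.10, the transcription factor Zbtb20 0.17, -0.011, -0.048 and -0.12, and Tiparp -0.32, 0.12, -0.29 and 0.49. Usp2, Pnisr, Ttc14, Dock4, Acsl3, Hnrnpdl, Tm2d2 and Cnn3 passed too. Adjusted over the list alone, 27 of the 133 listed genes in this test passed, against 7 over all genes, and taking each list by itself 5 of 5 myelin genes did, with Mal at -0.21, 0.43, -0.11 and -0.10 and Mobp at -0.30, 0.45, -0.057 and -0.096, while 0 of the 5 passed by limma over all genes (adjusted p 0.0677 for Mal to 0.17 for Cnp, unadjusted p under 0.05 in 5). By the same count 5 of 9 chaperones passed (2 over all genes), 4 of 10 astrocyte markers, 3 of 4 glucocorticoid-responsive genes (1 over all genes), and 0 of 9 neuronal, 0 of 11 presynaptic, 0 of 9 glutamate receptor and 0 of 10 oxidative phosphorylation genes. No adjustment was made over the 38 lists. With 564 of 3062 genes under an unadjusted p of 0.05, passing within a short list is not particular to that list. With a sample left out 4 genes passed without sample 11, 8 without sample 13, 7 without sample 15 and 10 without sample 17, and 35 passed with variances not squeezed.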

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

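In this part, the comparison of other probe sets of the same gene was set down before its result was seen, and the tests of the control transcripts, of the myelin, choroid plexus and ependymal markers and of Gh were chosen only after the patterns were seen, as was the condition that the genes tested lie above background.

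Of 175 named genes, 32 had 1 sample far from the other 3, by a gap of more than 0.829 of the whole range; chance alone gives this in about 1 group in 20, and in 26 of the 32 the other samples included equal values, which shrink their range. Sample 11 stood high for Amigo2 (6.53), Eomes (4.79), Cx3cr1 (7.71), Slc4a1 (3.66), Uqcrc1 (10.93), Pfkm (10.67) and Xist (4.23) and low for Drd2 (4.21), Ifit3 (5.15), Tpi1 (11.37), C1qb (8.02) and C1qc (7.91). Sample 13 stood high for Mobp (10.72), Ccdc153 (4.93), Rarres2 (6.67), S100a8 (3.65), Pomc (5.74) and Ndufa1 (11.50) and low for Nlgn1 (6.997) and Oasl2 (3.28). Sample 15 stood high for Gria1 (11.35), Acta2 (7.64), Tagln (6.42) and Prm2 (4.06). Sample 17 stood high for Mki67 (3.21), S100a9 (3.71), Avp (4.16), Ifit1 (4.04) and Plk5 (7.62) and low for Camk2a (11.72), Tcf7l2 (3.99) and Zbtb16 (7.58). All of these are log2 levels.

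Among 30 list means, 3 had 1 sample apart: dentate granule cell markers in sample 17 at 0.16, astrocyte markers in sample 11 at -0.085 and mural markers in sample 15 at 0.19. Among 10 control differences, that of bioB was apart in sample 13 at 0.21 against 0.25 in the other samples. None of the 19 genes whose probe sets agreed had a sample apart by this measure.

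The 5' ends gave less signal in samples 15 and 17, with a Gapdh 3' minus 5' difference of 2.64 and 3.79 against 0.62 and 0.62 in samples 11 and 13. Of 13444 probe sets, 272 fell with that difference by a slope under -0.2 and 18 rose by more than 0.2, and in 244 genes the other probe sets had a median slope of 0.0117 (95% bootstrap interval 0.00637 to 0.0169) against -0.297 for the falling ones, which argues against lower levels of these transcripts; for Hpca, chosen after its values were seen, 1 probe set went from 8.75 in sample 11 to 5.15 in sample 17 and the other from 11.70 to 11.65. The ready-labelled hybridisation controls kept their 3' minus 5' difference within a median range of 0.0673 against 2.20 for the mouse controls, which argues against hybridisation or scanning as the cause. The poly-A controls had a median range of 0.359, above the highest of the hybridisation controls (0.0846). RNA broken before their addition would not give this. Yet only dap had both probe sets above background (1.37, 1.46, 1.62 and 1.88 in samples 11, 13, 15 and 17). With its middle probe set under background, thr stood at 1.85, 1.91, 2.99 and 3.47 in the same samples. The ranges of lys and phe, whose middle probe sets were also under background, were 0.20 and 0.156. The labels do not say when such controls were added. These reservations were made after the values were seen. With them, breakage in the tissue and shorter amplified RNA cannot be told apart. No biological difference between groups was tested as an explanation, since the design has 1 group.

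Myelin genes and Ttr were higher in sample 13, by 0.53 for the myelin list against the mean of the other samples. What lies behind the 3' minus 5' difference is argued against by the difference of 0.621 between samples 13 and 11. These had the same Gapdh difference, and 95% of random lists stayed under 0.124. The highest deviation of the astrocyte, microglia and endothelial lists in sample 13 was 0.0362. That argues against a lower share of neurons with these cell types raised in step with myelin. It cannot argue against fewer neurons beside more oligodendrocytes alone, which was not tested. The neuronal list itself deviated by 0.043 in sample 13. Of the other choroid plexus markers 7 of 12 were highest in sample 13, and of the ependymal markers 8 of 10, against 20% of all 9187 dim genes, but in that sample 0 of the 12 and 1 of the 10 were above background and genes of 1 dissection are not independent, so these ranks decide nothing; with no filter on level the spreads of both lists passed against random lists (adjusted p 0.00076 for each), Ttr being in the first. More tissue from the border of the ventricle in that dissection stays open as a candidate explanation, with Ttr at 9.84 there. The design names no biological difference between the samples, so none was tested as an explanation.

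Gh, the growth hormone gene, gave more signal in sample 13 in all 4 of its probe sets, which was noticed after its values were seen; there they lay at 5.85 to 6.55, 1 of 4 above the background of 6.03, and at 2.80 to 4.80 in the other samples, so the size of the difference, 2.82 as a median, is uncertain. Noise of dim probe sets stays open, although the lowest difference was 1.91. Pituitary tissue stays open too: Prl, Pomc and Cga differed by a median of 0.278, but all 3 were under background, where a small rise would not show, and Pomc stood apart in sample 13 at 5.74. Signal from another transcript that binds these probes was not tested, and the design gives no biological explanation to test.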

How the results depend on the processing

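No paired analysis was possible because the series has 1 group. The 3' minus 5' covariate, the omission of samples 15 and 17, the probe-set test with all its settings and the repeated normalization of the hybridisation controls were chosen only after the data were seen. Genes above background ranged from 6509 to 10217 over 10 settings, around 9006. The test of single probe sets by limma gave 0 calls in all 14 other settings, beside 409 unadjusted p under 0.05 in the setting reported. It had almost no power on simulated data with variances spread as fitted, so the count of 0 says little about stability. Lists passing ranged from 4 to 13 over 11 settings, around 9: 4 passed with deviations divided by the squeezed SD, and 4 to 10 with 1 sample left out (4 without sample 15, 7 without sample 13). The 13 came from 38 lists tested with no filter on level, against 30 tested in the setting reported. Immediate early genes passed in all 11 settings, myelin genes and chaperones in all but the omission of sample 13 (adjusted p 0.119 and 0.276), and glucocorticoid-responsive genes in all but the scaling (0.135). CA1 and microglial markers passed in 8 settings, dentate markers in 6, clock genes in 4 and ribosomal proteins in 3; with the 3' minus 5' covariate 8 lists passed, 7 of them among the 9. Over all lists and settings 282 outcomes stayed on their side of the threshold, 29 calls were lost and 16 gained, 6 of these by meningeal markers. The median difference between arrays was 0.0756 to 0.103 with 1 sample left out, the highest without sample 13, and the median SD of hybridisation controls 0.0238 (without sample 11) to 0.0505. Genes whose probe sets agreed numbered 19, with 4 to 10 when 1 sample was left out, 8 at an adjusted p of 0.01, 13 without a filter, 13 after quantile normalization again and 35 with variances not squeezed. For 131 of 175 named genes the SD moved by over 1.5 times with the omission of at least 1 sample: 37 without sample 11, 34 without sample 13, 24 without sample 15 and 36 without sample 17, so an SD over 4 samples often rests on 1 of them. It moved as far for 11 genes with quantile normalization again and for 6 with median centring. Fewer samples enter each fit with 1 left out; for the other settings that changed a count the cause was not tested. Genes near the background of 6.03 are the least certain.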

Other observations

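In this part, the test of probe sets and the major histocompatibility, astrocyte and GABA receptor values were chosen only after the results were seen; the test of neighbouring genes was set down before its result. Adjustment over a list alone makes no allowance for the number of lists looked at.

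Of the class I major histocompatibility genes, which present peptides to T cells, the 3 above background were highest in sample 15 and lowest in sample 11. In samples 11, 13, 15 and 17, the 2 probe sets of H2-K1 deviated by -0.23, -0.089, 0.39 and -0.073, those of H2-D1 by -0.23, 0.0032, 0.28 and -0.059 and those of B2m, the shared light chain, by -0.19, -0.015, 0.22 and -0.015. Adjusted over the list alone, 3 of 3 passed the limma-based test of probe sets (adjusted p 0.00125, 0.00269 and 0.00437), and over all genes none did (0.0582, 0.0917 and 0.116). Whether the probe sets of H2-K1 and H2-D1, which are related genes, also bind each other's transcripts was not tested, so their agreement may not be independent. The list had too few members above background for the test of lists, and with no filter on level it did not pass that test (adjusted p 0.0559). Microglial markers were also highest in sample 15 and lowest in sample 11.

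Of 10 astrocyte markers in that test, 4 passed with limma adjusted over the list alone and 0 over all genes (the lowest adjusted p 0.0679, unadjusted p under 0.05 in each of the 4), and they did not share an order. Gfap, the filament protein of astrocytes, deviated by -0.35, 0.32, -0.038 and 0.069 and the transcription factor Sox9 by -0.034, 0.19, -0.062 and -0.094, while the calcium-binding S100b deviated by -0.14, -0.098, 0.14 and 0.10 and the secreted chaperone Clu by -0.049, -0.037, 0.065 and 0.020. Of 6 GABA receptor genes 2 passed adjusted over the list alone and 0 by limma over all genes (adjusted p 0.0916 and 0.0923, unadjusted 0.00161 and 0.00199): the subunit genes Gabra2, which deviated by 0.73, -0.16, -0.74 and 0.17, and Gabrb2, by 0.11, 0.033, -0.15 and 0.009.

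A hypothesis was that part of the spread is inherited in linked blocks of the genome, in which case the 150 genes with the largest spread after the 3' minus 5' covariate would lie near each other more often than chance. They formed 31 pairs within 10 measured genes, against a median of 24 and a 95th percentile of 33 in 10000 random sets of the same level (one-sided permutation p = 0.114), so the data neither bear this out nor exclude it.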
